A study of Homo sapiens with 8 samples.

How the data were processed

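mTOR, the serine/threonine kinase of the nutrient and growth-factor pathway of the same name, was immunoprecipitated with its cross-linked DNA from LNCaP cells, an established human prostate cancer line that responds to androgen. The cells carried either an empty short-hairpin vector (shEV) or a hairpin against FoxA1 (shFoxA1), a pioneer transcription factor that opens chromatin for other factors. They were deprived of androgen for 48 h in medium with 2% charcoal-stripped serum and then given the vehicle ethanol (EtOH, 0.1%) or 10 nM R1881, a synthetic androgen, for 24 h. The sequencing was paired-end with 150 bp reads. The series has 8 libraries, 4 from mTOR chromatin immunoprecipitation and 4 from input DNA, with 1 library for each combination of hairpin, treatment and material. The peak lists of the 4 immunoprecipitated libraries were used, and the inputs were not analysed here.

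Per the submitters' processing notes, the tools used upstream were Trimmomatic 0.36, BWA 0.7.12, Picard 2.0.1, MACS2, HOMER 4.11.1 and deepTools 3.5.0, with the genome build hg38; the notes as used here give no role or order for them. Per the file headers, each list is the output of HOMER's peak annotation, and its peak names carry a single library each, so peaks were called per library. The control given to the peak caller, its threshold and the handling of duplicate reads are not given in the sources used here. The deposited score of a peak is the authors' own value from the peak calling, and its exact definition is not given in the sources used here; it was used to describe, rank and filter peaks within their own list and never to compare lists. The deposited fraction of G and C bases in each peak, from 0 to 1, is a property of the reference sequence and was printed as a percentage. Annotation classes, the nearest gene and the signed distance to its transcription start site (TSS) were taken as deposited. Start and end are given as in the files, counted from 1. No read totals accompany the lists, so the depth of each library is unknown, and a longer list can come from a deeper or more enriched library as well as from more bound sites.

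Peaks on chromosomes 1 to 22, X and Y entered every comparison, and those on other sequences are given apart. A peak of 1 list was called shared when a peak of the other list overlapped it by at least 1 bp. For a pair of libraries, a gained peak is a peak of the first list with no overlap in the second, and a lost peak is a peak of the second with none in the first; both terms describe presence in thresholded lists, not a measured difference in occupancy. The overlap expected by position alone was measured by moving the other list round each chromosome by a random distance in 100 draws. The peaks of all 4 lists were merged into union regions, each with 1 of 15 presence patterns. Whether the R1881 response of a region went the same way with both hairpins was described by an odds ratio over regions that were gained or lost in both independent pairs; the pairs share no library. The same was done for the knockdown in EtOH against the knockdown in R1881. Shares carry Wilson 95% intervals and odds ratios 95% intervals on the log scale; both cover counting error only. With 1 library per group no p-value is given.

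A peak was assigned to the nearest gene given in the file when it lay within 50 kb of its TSS. A peak said to be at a gene is one assigned in this way, and it can lie in a repeat or in an intron of another gene. The 12 gene lists were fixed before the data were examined: androgen-induced genes, androgen-repressed genes, prostate luminal transcription factors, glycolysis, TCA cycle and respiratory chain, lipid and sterol synthesis, mTOR pathway, ribosomal proteins, cell cycle, neuroendocrine markers, basal and mesenchymal markers, and genes of unrelated tissues. All of their members were matched to gene identifiers through a RefSeq table of the assembly GRCh38.p14, which was used only for names, gene lengths and the number of coding genes per chromosome; it holds 20037 protein-coding genes on the chromosomes used. For each library the share of list genes with a peak was placed among 10000 random lists of the same size. For each pair, the gained minus the lost peaks of a list were placed among 10000 random lists of genes matched on the number of peaks per gene over both libraries. For regions present in exactly 2 lists the number was taken over all 4 libraries. The matching used bins of peak number, the highest without an upper limit. Random genes said to have as many peaks are genes of the same bin, and their exact numbers can differ. A list outside the central 95% of its random lists is said to stand apart, which describes these libraries and is not a test. With 12 lists placed in each of 4 pairs, some would lie outside by chance alone. Some genes belong to 2 lists, among them ACSL3 (androgen-induced and lipid) and SPDEF (androgen-induced and luminal).

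The genes named were set by a rule fixed before the data were examined. For each pair these were the 10 protein-coding genes with the highest-scoring gained peak and the 10 with the highest-scoring lost peak, with 1 peak per gene and ties settled by the wider peak. From each list 2 to 4 members with the highest-scoring gained or lost peak could be given as examples. FOXA1, MTOR, KLK3, KLK2, TMPRSS2, FKBP5 and SLC45A3 are given in every library; some other genes that the rule selects are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

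The alternatives set before the data were examined were an overlap of at least 50% of the peak asked about (midpoints within 500 bp for union regions), the upper part of each list by score (at or above its median), the 10000 highest-scoring peaks of each list, lists without satellite, simple, low-complexity and rRNA repeats, and TSS distances of 10 kb or without a limit. Comparisons chosen after the data were seen were the 10000 highest-scoring peaks of a list against all peaks of the other, random lists matched on gene length, gene lists near regions present in exactly 2 lists, and odds ratios within bins of GC content. A planned comparison of sequence motifs was not run, since no genome sequence was used here.

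The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. Overlap calls on simulated lists of 2400 peaks differed from a direct comparison in 0 cases. For the overlap of 2 libraries, a simulated list of 24000 peaks thinned to 60.3% of its peaks was recovered at 60.3%, and unrelated lists shared 2.89% of peaks against 2.89% after shifting. For the agreement of the R1881 response, 60000 simulated regions without a shared response gave an odds ratio of 1.04 (0.949 to 1.15), and with a shared response in 10% of regions 1.82 (1.66 to 2.00). For gene lists over 20000 simulated genes, 3.50% of unrelated lists lay outside the central 95%, and 99.5% of lists with 25 planted gained peaks lay above it.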

Results

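Chromatin bound by mTOR was profiled in LNCaP prostate cancer cells with the empty vector (shEV) or the FoxA1 hairpin (shFoxA1), each after vehicle (EtOH) or the synthetic androgen R1881. The 4 deposited peak lists on chromosomes 1 to 22, X and Y held 24948 peaks for shEV EtOH, 26074 for shEV R1881, 35121 for shFoxA1 EtOH and 39570 for shFoxA1 R1881. They covered 14.2, 14.5, 21.1 and 23.6 Mb, with median peak widths of 452, 445, 471 and 470 bp. Each group is a single library, so no difference below has a replicate check.

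The FOXA1 locus, the target of the hairpin, carried peaks in every library. Within 50 kb of its TSS there were 3 peaks in shEV EtOH, 3 in shEV R1881, 5 in shFoxA1 EtOH and 5 in shFoxA1 R1881. A peak in exon 2 of 2, about 2.8 kb from the TSS (chromosome 14, 37592253 to 37592556 in shEV R1881), was present in all 4 lists, and a promoter peak (37594642 to 37595682, centred 87 bp from the TSS) was called in shFoxA1 EtOH; in shFoxA1 R1881 a peak assigned to the neighbouring gene TTC6 overlaps it. These are binding data, so the level of FoxA1 itself, and with it the strength of the knockdown, was not measured here.

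Most mTOR peaks lay in introns or between genes. The share of each class in the genome was not computed, so the shares here describe the lists and show no preference of mTOR. Introns held 35.5% of the peaks in shEV EtOH, 37.4% in shEV R1881, 36.5% in shFoxA1 EtOH and 38.2% in shFoxA1 R1881, and intergenic sequence held 49.3%, 48.5%, 44.7% and 44.7%. Promoters held 9.80% (95% interval 9.44 to 10.2) in shEV EtOH, 8.90% (8.56 to 9.25) in shEV R1881, 12.6% (12.3 to 13.0) in shFoxA1 EtOH and 11.2% (10.9 to 11.5) in shFoxA1 R1881. A large part of each list was annotated to repeats, from 62.0% in shFoxA1 R1881 to 70.6% in shEV EtOH. Peaks in repeats were kept, and how well reads map there was not assessed. LINE elements, a class of retrotransposons that includes L1 and L2, took 36.8%, 35.6%, 32.4% and 31.9% of the 4 lists, and long terminal repeats of endogenous retroviruses took 19.9%, 18.8%, 17.7% and 16.3%. The strongest peaks were richer in long terminal repeats than the weakest: in shEV EtOH they made up 34.1% of the highest-scoring 20% and 10.4% of the lowest-scoring 20%, while promoters made up 6.27% and 12.3%.

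In each list the genes that androgen is known to induce carried mTOR peaks more often than other coding genes. Among the 35 androgen-induced genes, 22 had a peak within 50 kb in shEV EtOH, 28 in shEV R1881, 27 in shFoxA1 EtOH and 31 in shFoxA1 R1881, above the 99th percentile of random lists in every library. All coding genes stood at 36.5%, 37.5%, 49.1% and 51.6%. Of the 10 androgen-repressed genes, 9, 7, 9 and 8 had a peak (percentiles 99.98, 97.9, 99.4 and 96.05). Of the 20 luminal transcription factors, the regulators of the prostate's secretory cells, 13, 12, 16 and 17 did (percentiles 99.4, 97.85, 99.7 and 99.9). The excess was therefore not particular to the androgen-induced genes, and the random lists were not matched on expression. The mTOR pathway had a peak at 23, 18, 26 and 30 of its 40 genes (percentiles 99.5, 83.5, 97.7 and 99.9), and in shEV R1881 it did not stand apart. Lipid and sterol synthesis had 16, 14, 20 and 22 of 30 genes with a peak and glycolysis 14, 14, 20 and 19 of 26. Genes of unrelated tissues lay at the other end, with 4, 5, 7 and 9 of 30 (percentiles 0.335, 0.810, 0.305 and 1.01). The TCA cycle and respiratory chain had 10, 11, 18 and 16 of 39 genes with a peak, ribosomal proteins 18, 17, 36 and 32 of 53, the cell cycle 11, 16, 20 and 20 of 35, neuroendocrine markers 7, 9, 10 and 10 of 18, and basal and mesenchymal markers 3, 9, 8 and 8 of 20. Against random lists matched on gene length, the unrelated tissues moved inside the central 95% in both R1881 lists, with percentiles of 2.56 and 3.77. So did the androgen-repressed genes in shEV R1881 (96.7), the mTOR pathway in shFoxA1 EtOH (92.6) and lipid and sterol synthesis in shFoxA1 R1881 (95.2), while the ribosomal proteins in shFoxA1 R1881 moved outside it (99.9).

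The first comparison asks where mTOR peaks appear and disappear when androgen is given to cells with the empty vector. R1881 was followed by new mTOR peaks around known androgen targets. Near the 35 androgen-induced genes 42 peaks were gained and 14 lost, and 23 of these genes had at least 1 gained peak. Near the 10 androgen-repressed genes 1 peak was gained and 8 were lost. The net gains of 28 and -7 stood apart from random lists with as many peaks (percentiles 99.99 and 1.07). Across the genome 11739 peaks were gained and 10626 lost, so that the balance of the 2 directions was close to even, at 52.5% gained.

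FKBP5, a cochaperone gene and a classical androgen target, gained the highest-scoring peak of the androgen-induced list: score 339, in intron 1 at chromosome 6, 35722391 to 35722885, 5945 bp from a TSS. SLC45A3, which encodes the prostate antigen prostein, gained an intergenic peak at -18711 bp from its TSS (chromosome 1, 205698823 to 205699617, score 288). EAF2, which encodes an elongation-factor partner, gained an intronic peak (score 157). On the androgen-repressed list UGT2B15, which encodes an enzyme that glucuronidates androgens, lost an intronic peak (chromosome 4, 68665658 to 68666047, score 203) and gained a promoter peak (score 58). OPRK1, the kappa opioid receptor gene, and CCN3 lost intergenic peaks with scores of 58 and 42.

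The gained peak with the highest score near any coding gene lay at -33199 bp from the TSS of the myosin light chain gene MYL10 (chromosome 7, 101661938 to 101663053, score 1444). It was followed by peaks at CEP120, a centrosomal gene (790), TEX264, an endoplasmic reticulum autophagy receptor (728), TUT7, an RNA uridylyltransferase (636), ATAD2, a bromodomain ATPase (592), and TACC2, a gene for a spindle-associated protein (577). PNLIP, TBRG1 and RGS2 shared a score of 448, and ADAM2 had 406. Of the gained peaks just named, all but those at MYL10, CEP120, TACC2 and ADAM2 were annotated to repeats. The lost peaks, scored in shEV EtOH, were led by ERCC6L2, a DNA repair helicase (327), TEKT3 (314), the zinc-finger repressor ZNF91 (301), the endocytic adaptor EPN1 (289), TCIM and the mitochondrial calcium regulator MCUR1 (276 each), CALHM6 (239), and RLN1, SLC2A8 and RELL1 (227 each). All of these lost peaks but those at EPN1, MCUR1 and SLC2A8 were annotated to repeats.

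Beyond the androgen lists, the cell cycle and the basal and mesenchymal markers stood apart. Lipid and sterol synthesis had 24 gained and 12 lost peaks, a net of 12 at the upper edge of the central 95% of its random lists (-8 to 12); HMGCS1, which encodes an early enzyme of sterol synthesis, gained a peak with a score of 146, and FASN, the fatty acid synthase gene, gained 1 with 76. The cell cycle list had 12 gained and 2 lost peaks, a net of 10 at the upper end of its random range (-7 to 10, percentile 97.9). Among them were gained peaks at the replication helicase gene MCM7 (95), at cyclin D1 (CCND1, 67) and at CDK1 (58). Basal and mesenchymal markers had 11 gained and 0 lost peaks (percentile 99.98), at genes such as TP63, the basal cell transcription factor (76), and CDH2, N-cadherin (58). Only 3 of these 20 genes had a peak in shEV EtOH, so few could be lost. The mTOR pathway had 9 gained and 14 lost peaks, a net of -5 (percentile 10.0). Its strongest gained peak lay in MTOR (379), followed by PRR5, a subunit of mTOR complex 2 (191), and EIF4E, the cap-binding factor (114), while EIF4EBP1 lost a peak with a score of 76. Net values were 5 for luminal transcription factors, 4 for glycolysis, 1 for the TCA cycle and respiratory chain, -3 for ribosomal proteins, 1 for neuroendocrine markers and -1 for genes of unrelated tissues, all inside the central 95%.

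Of the shEV EtOH peaks 57.4% (56.8 to 58.0) were shared with shEV R1881, against 1.11% after shifting. Gained and lost peaks were weaker than shared ones, with a median score of 42 against 85 for the shared peaks of shEV R1881. With the 10000 highest-scoring peaks of each list the net of the androgen-induced list was 13, that of the androgen-repressed list 0, that of the cell cycle 2 and that of the basal and mesenchymal markers -1.

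**Figure D1:**
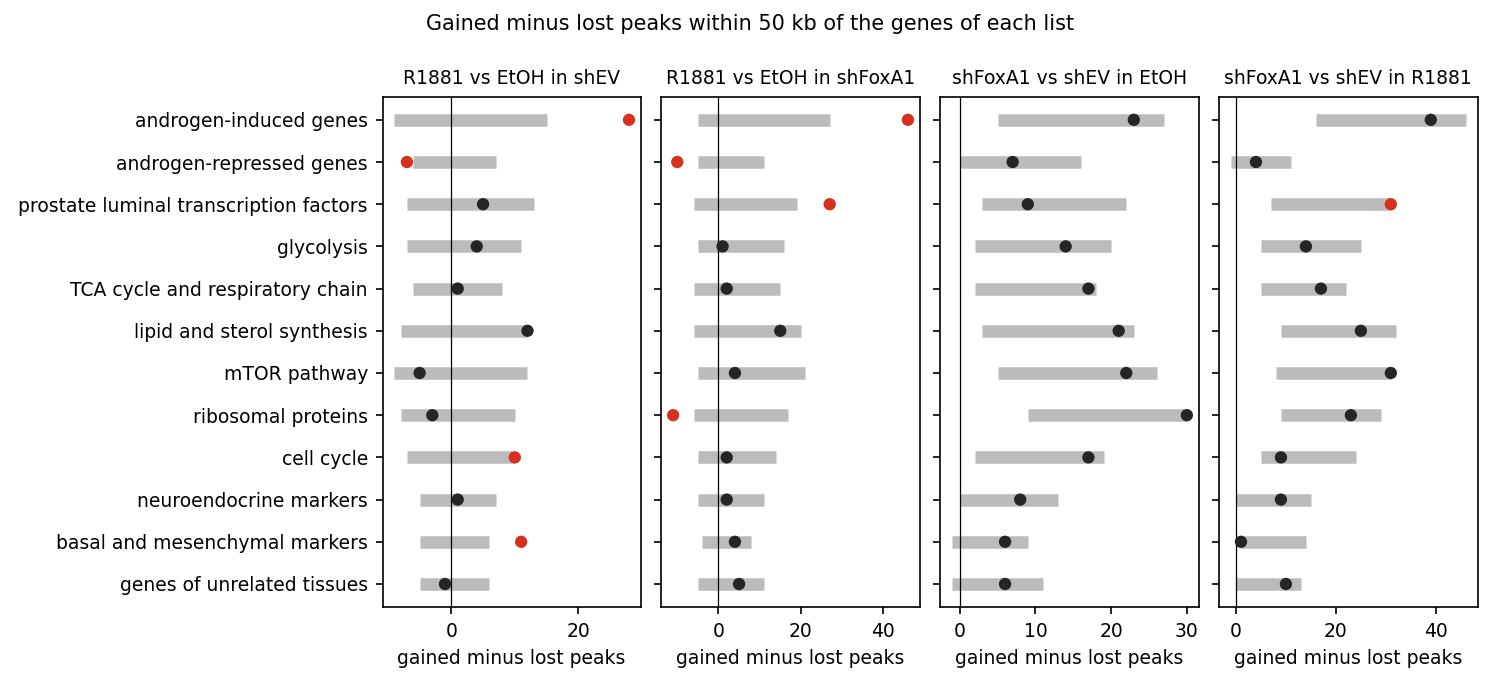
Gained minus lost mTOR peaks within 50 kb of the genes of each of 12 lists (horizontal axes, number of peaks), for the 4 pairs of libraries. Points are the lists, red where the percentile among 10000 random lists matched on peaks per gene is outside the central 95%, and grey bars are those central ranges, whose ends tied values can touch; the androgen-induced genes lie to the right of the grey bar in both R1881 panels, at 28 and 46.

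The second comparison repeats the androgen treatment in cells with the FoxA1 hairpin. Both androgen lists stood apart again, while the other lists that did so were different ones. Near the 35 androgen-induced genes 62 peaks were gained and 16 lost, with a gained peak at 27 of them, and near the 10 androgen-repressed genes 5 were gained and 15 lost. The net values of 46 and -10 lay at percentiles 100 and 0.075. Luminal transcription factors gained 37 peaks and lost 10 (net 27, percentile 99.9), and ribosomal protein genes gained 12 and lost 23 (net -11, percentile 0.295). Genome-wide 17624 peaks were gained and 13173 lost, 57.2% of them gained.

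FKBP5 again led the androgen-induced list, with a peak at nearly the same place (chromosome 6, 35722314 to 35722958, score 466), and gained peaks also lay at EAF2 (358) and SLC45A3 (164, chromosome 1, 205698825 to 205699612). Lost peaks on that list included an intronic FKBP5 peak 516 bp from a TSS (134) and a peak at SORD, the sorbitol dehydrogenase gene (84). Among the androgen-repressed genes UGT2B15 and OPRK1 lost intergenic peaks (75 and 66), while CCN3 gained an intergenic peak (112, chromosome 8, 119410500 to 119411009) at the place of the peak it lost with R1881 in shEV. The luminal list gained peaks at the ETS factor SPDEF (83), at FOXA1 (74) and at EHF (65), and lost peaks at GRHL2 (123) and HOXB13 (75). The ribosomal protein genes lost promoter peaks at RPS16 (103) and RPL37 (58), and gained an intronic peak at RPLP1 (65).

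The highest-scoring gained peaks near coding genes were at GREB1L (933), a relative of the hormone-responsive gene GREB1, CEP120 (838), CCT8L2 (806), TACC2 (624), the receptor tyrosine kinase gene ALK (594), SGPP2, a sphingosine phosphate phosphatase gene (537), MYL10 (522), COL4A2-AS2 and TEX264 (494 each) and FKBP5 (466). The GREB1L region had a peak in both shEV lists too, so shFoxA1 EtOH was the exception; the 9 others had a peak in shEV R1881 and none in shEV EtOH. CEP120, TACC2, MYL10 and TEX264 had also been among the 10 with the empty vector. The peaks at GREB1L, CCT8L2, ALK, TEX264 and FKBP5 were annotated to repeats, those at CCT8L2 and ALK to simple repeats. COL4A2-AS2 is by its name an antisense gene of COL4A2, and its peak lay in intron 31 of 47 of an overlapping transcript. The highest-scoring lost peak was at MAMDC2 (674, chromosome 9, 70038185 to 70038557), in a simple repeat of TGGAA units and a region with a peak in the 3 other lists. It was followed by LONRF2 (284), SIMC1 and ARSH (235 each), TFB1M, the growth-factor homologue FGF13 and the heparan sulfate enzyme HS6ST2 (223 each), ACSBG2 (211), and the potassium channel gene KCNQ5 and the iron reductase gene CYBRD1 (200 each). All of these lost peaks but those at ACSBG2 and CYBRD1 were annotated to repeats.

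Lipid and sterol synthesis had 26 gained and 11 lost peaks (net 15, percentile 87.6), with gained peaks at the promoters of ELOVL5, a fatty acid elongase (112), and SREBF1, the lipogenic transcription factor (83). The mTOR pathway had 23 gained and 19 lost (net 4, percentile 28.8): DDIT4, which encodes a stress-induced mTOR inhibitor, gained a peak with a score of 83. RICTOR, the gene of the defining subunit of mTOR complex 2, gained an intronic peak (83) and lost another near its TSS (103), and RPTOR, that of complex 1, lost 1 with 123. Net values were 1 for glycolysis, 2 for the TCA cycle and respiratory chain, 2 for the cell cycle, 2 for neuroendocrine markers, 4 for basal and mesenchymal markers and 5 for genes of unrelated tissues, all inside the central 95%. Of the shFoxA1 EtOH peaks 62.5% (62.0 to 63.0) were shared with shFoxA1 R1881, against 1.79% after shifting. With the 10000 highest-scoring peaks of each list the net was 10 for the androgen-induced list, 0 for the androgen-repressed list, 3 for luminal factors and 2 for ribosomal proteins, where the direction turned.

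The next comparison asks whether regions gained or lost with androgen in the empty-vector libraries go the same way in the FoxA1-hairpin libraries. The merged lists gave 61118 union regions, of which 11634, or 19.0%, had a peak in all 4 libraries. A further 3221 regions had a peak in both R1881 libraries and neither EtOH library, and 1964 had the reverse. The crossed combinations, gained with 1 hairpin and lost with the other, were fewer, at 1094 and 1298 regions. The odds ratio for the R1881 response going the same way with both hairpins was 4.45 (4.04 to 4.91). For the knockdown, the odds ratio for going the same way in EtOH and in R1881 was 1.76 (1.56 to 1.98), from 4222 regions with a peak in both shFoxA1 lists only and 591 with a peak in both shEV lists only. Within 5 bins of GC content the R1881 odds ratio lay between 2.27 (1.79 to 2.89) and 8.83 (6.82 to 11.4). The knockdown odds ratio lay between 1.13 (0.904 to 1.41) and 1.52 (1.08 to 2.14), below the value over all regions in every bin, and in 2 of the 5 its interval included 1. Single-library regions were numerous, with 12017 in shFoxA1 R1881 and 8994 in shFoxA1 EtOH, against 4418 in shEV R1881 and 3994 in shEV EtOH.

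**Figure D2:**
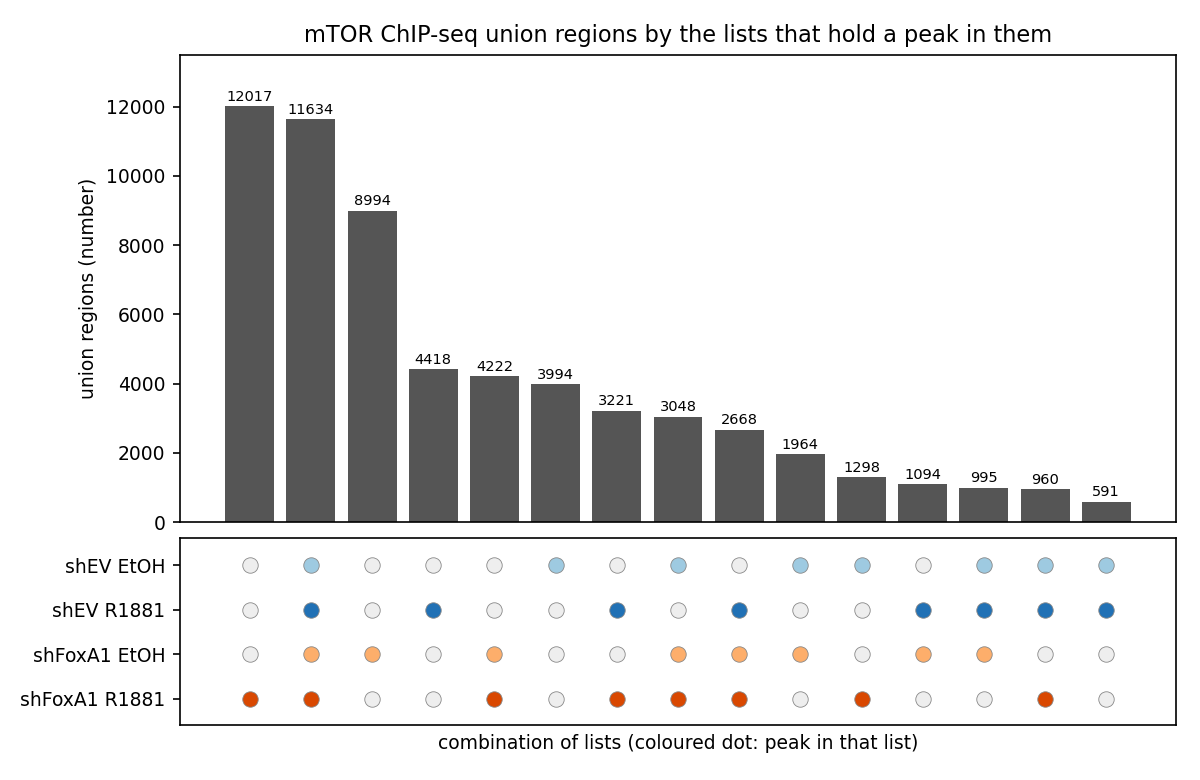
Number of union regions (vertical axis) for each of the 15 combinations of lists that hold a peak in the region; coloured dots under each bar mark the lists with a peak. The tallest bars are the regions of shFoxA1 R1881 alone (12017) and of all 4 lists (11634), and the regions of both R1881 lists (3221) exceed those of both EtOH lists (1964).

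Regions present in both R1881 lists and neither EtOH list lay near many known androgen targets. Counted by direct overlap, 3290 peaks of shFoxA1 R1881 had a peak in shEV R1881 and none in the EtOH lists. Of these 46.6% were intronic and 4.62% lay in promoters. They touched 15 of the 35 androgen-induced genes, against 5.43 for random genes with as many peaks (percentile 100), among them CAMKK2, EAF2, FKBP5, GNMT, KRT8, NDRG1, PMEPA1, SLC45A3, SORD, TPD52, TRPM8, ZBTB10 and ZBTB16. They touched 9 of the 30 genes of lipid and sterol synthesis, against 3.51 (percentile 99.8), among them ACACA and FASN, the core enzymes of fatty acid synthesis, the desaturase and elongase genes FADS1 and ELOVL5, the sterol gene HMGCS1, SCAP and SREBF1, which encode a sterol-sensing escort protein and the lipogenic factor it carries, and LPIN1. None of the 10 androgen-repressed genes and none of the 39 genes of the TCA cycle and respiratory chain was touched, the latter at percentile 4.42. From the mTOR pathway only EIF4E and MTOR itself were (percentile 14.9), and the other lists lay inside the central 95% as well. These members were chosen after the values were seen. Among coding genes the highest-scoring of these regions were at CEP120, CCT8L2, TACC2, ALK, SGPP2 and MYL10, those at CCT8L2 and ALK in simple repeats.

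Of the 11739 peaks gained with R1881 in shEV, 6137 or 52.3% (51.4 to 53.2) had a peak in shFoxA1 R1881, and 37.6% had none in either shFoxA1 list. The share depended on the strength of the peak, from 36.1% in the lowest-scoring 20% to 88.6% in the highest-scoring 20%. Peaks of shEV R1881 shared with shEV EtOH were found in shFoxA1 R1881 in 88.4% of cases. Their share rose from 67.6% in the lowest-scoring 20% to 99.0% in the highest-scoring 20%, so the gap to gained peaks was narrower among strong peaks. Regions in both EtOH lists only touched 3 androgen-induced genes, FKBP5, HERC3 and SORD. With the upper part of each list by score the regions in both R1881 lists only numbered 1835, with the 10000 highest-scoring peaks 930, and at that setting 29.6% of regions were in all 4 lists.

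The knockdown comparison in vehicle sets the shFoxA1 library against the shEV library without androgen. The shFoxA1 EtOH list held many more peaks than the shEV EtOH list, with 17281 gained and 6994 lost, 71.2% of them gained. Promoters made up 14.1% of the gained and 5.23% of the lost peaks, and the median GC content was 46.4% against 40.4%. LINE elements made up 48.2% of the lost peaks. Ribosomal protein genes had 35 gained and 5 lost peaks within 50 kb, and 28 of the 53 genes had at least 1 gained peak; the net of 30 lay inside the range of random genes with as many peaks (percentile 97.1).

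The highest-scoring gained peaks lay at the promoter of TXNIP, a glucose-regulated inhibitor of thioredoxin (401, chromosome 1, 145996411 to 145996917), at the promoters of SMN2, a splicing-complex gene (375), and FOXJ3, a forkhead factor (297), and at SLC13A1, CNTNAP2 and the tubulin gene TUBB3 (284 each). SHH, the hedgehog ligand gene, and the deacetylase gene HDAC9 had 259 each, C19orf73 had 247 and HNRNPH1, a splicing regulator, 235. All 10 of these regions also had a peak in shEV R1881. The lost peaks were led by EPN1 (289), TCIM (276), UGT2B15 (203, the intronic peak also missing from the R1881 lists), ARMC3, HTR1F and COX18 (180 each), the receptor tyrosine kinase gene ROS1 (169), SPIN2B and ITGB3BP (158 each) and USP36 (147). All of these lost peaks but those at EPN1 and USP36 were annotated to repeats. The regions at ARMC3 and HTR1F also had a peak in both R1881 lists, and that at COX18 in shEV R1881. The other lost regions named had a peak in shEV EtOH alone.

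No list stood apart in vehicle. The net values, with the percentile in brackets, were 23 for androgen-induced genes (89.2), 7 for androgen-repressed genes (45.4), 9 for luminal factors (25.2), 14 for glycolysis (72.7), 17 for the TCA cycle and respiratory chain (94.8), 21 for lipid and sterol synthesis (93.7), 22 for the mTOR pathway (87.2), 17 for the cell cycle (93.6), 8 for neuroendocrine markers (69.2), 6 for basal and mesenchymal markers (79.7) and 6 for unrelated tissues (63.6). Examples were promoter peaks at PMEPA1, an androgen-responsive TGF-beta regulator (113), at TFAM, the mitochondrial transcription factor (84), at TFEB, the lysosomal master regulator controlled by mTOR (84), and at RPS16 (103), and an exonic peak at SREBF2 (123). Of the shEV EtOH peaks 72.0% (71.4 to 72.5) were shared.

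With R1881 the picture of the knockdown was similar in outline. There were 20899 gained and 7263 lost peaks, 74.2% of them gained, and promoters made up 2512 of the gained and 350 of the lost peaks. Luminal transcription factors gained 41 peaks and lost 10, a net of 31 at the upper end of its random range (7 to 31, percentile 97.9). They had gained peaks at GRHL2 (132), GATA2 (83), SPDEF (83) and FOXA1 (74) and lost peaks at SPDEF (50) and HOXB13 (42). The mTOR pathway gained 35 peaks and lost 4 (net 31, percentile 97.4, just inside the central range), with gained peaks at the stress sensors SESN1 (112) and SESN2 (102), at TFEB (102) and at AKT1S1, a subunit of mTOR complex 1 (92), and a lost peak at RPTOR (76).

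Promoters filled the top of the gained list: COX19, a mitochondrial copper chaperone gene (384, chromosome 7, 975352 to 975821), NIPA1, a magnesium transporter gene (332), TMEM39B (332), OSBPL11 (306), the deubiquitinase gene USP5 (306) and C1orf159 (269), with an exon 1 peak at the aminopeptidase gene NPEPPS (294). C8orf74, CNGA3 and DEFB136 had 269 each. All of these regions but that of DEFB136 also had a peak in both EtOH lists, so shEV R1881 was the exception there. The lost peaks were at MAMDC2 (667), TUT7 (636), STX11 (339), IL20RA and the ETS factor ELF1 (226 each), ADI1, FAM162A, CEP89 and CYB5A (214 each) and PTH (191). At MAMDC2 and ADI1 a peak was present in the 3 other lists, so shFoxA1 R1881 was the exception. The region at CYB5A also had a peak in shFoxA1 EtOH. The other lost regions named had a peak in shEV R1881 alone. All of these lost peaks but those at ADI1 and CEP89 were annotated to repeats.

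The remaining net values with R1881 were 39 for androgen-induced genes (percentile 86.8), 4 for androgen-repressed genes (33.2), 14 for glycolysis (43.1), 17 for the TCA cycle and respiratory chain (78.7), 25 for lipid and sterol synthesis (78.8), 23 for ribosomal proteins (75.4), 9 for the cell cycle (15.2), 9 for neuroendocrine markers (66.6), 1 for basal and mesenchymal markers (2.94) and 10 for unrelated tissues (87.0). Androgen-induced examples were a promoter peak at MAF (112), an intergenic peak at TMPRSS2 (102) and, lost, an intronic peak at IQGAP2 (95). Of the shEV R1881 peaks 72.1% (71.6 to 72.7) were shared. The shFoxA1 lists are longer, so an excess of gained over lost peaks is built into both knockdown comparisons, and its cause is left open. With the 10000 highest-scoring peaks of each list the luminal net was 5 and the androgen-induced net -5 in R1881 and -2 in EtOH.

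The ratio of peak numbers between the hairpins differed with GC content. At 60 to 65% GC the shFoxA1 EtOH list held 2.11 times as many promoter peaks and 2.05 times as many other peaks as the shEV EtOH list, and with R1881 the ratios were 2.23 and 2.34. Below 35% GC the ratios of other peaks were 1.16 and 1.01.

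**Figure D3:**
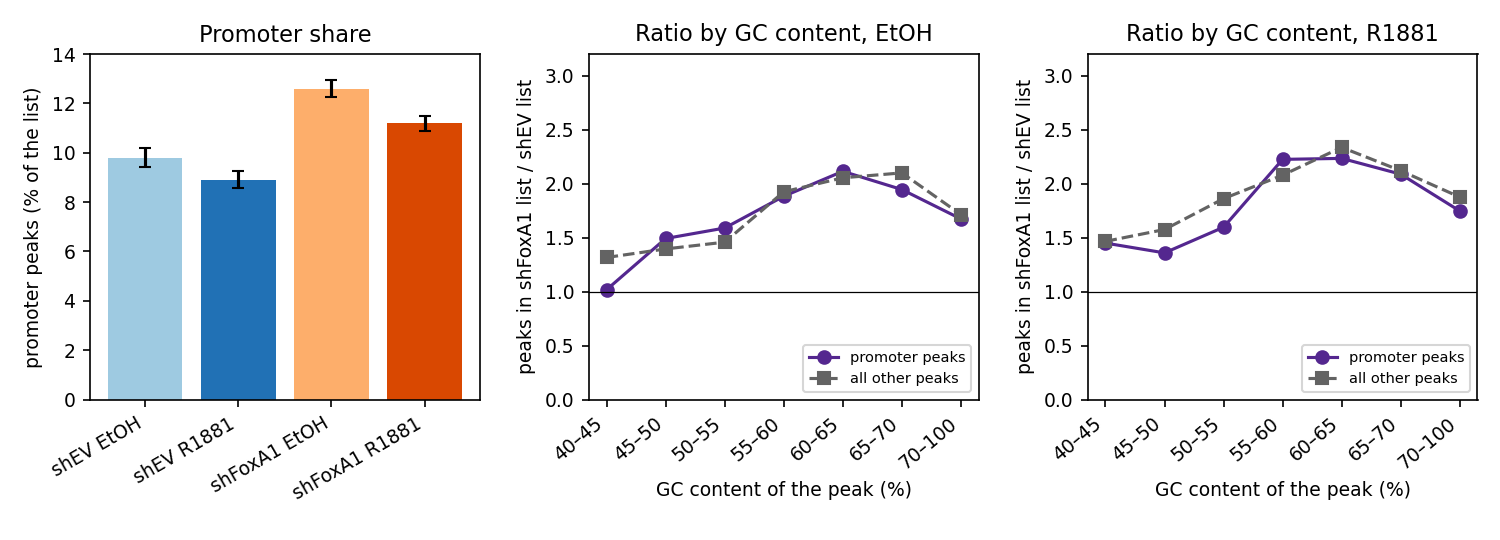
Left, share of peaks in promoters for each library (bars, percent of the list) with Wilson 95% intervals; the shFoxA1 lists stand at 12.6% and 11.2% and the shEV lists at 9.80% and 8.90%. Middle and right, number of peaks in the shFoxA1 list divided by the number in the shEV list, by GC content of the peak (percent), for promoter peaks (circles) and all other peaks (squares); both lines lie above 2 at 60 to 65% GC and are lower above 70%.

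Single loci of the androgen response and of the mTOR pathway show these differences directly. MTOR carried a peak in intron 4 of 57 with R1881 and none in the EtOH lists: chromosome 1, 11256204 to 11256704 in shEV (score 379) and 11256233 to 11256751 in shFoxA1 (score 57), about 6.1 kb from the TSS. At FKBP5 the intron 1 peak was present in both R1881 lists (339 and 466), while the EtOH lists held a peak at 35687906 to 35688871 (shEV, 105) and 35687759 to 35689039 (shFoxA1, 134) that the R1881 lists lacked. SLC45A3 had its upstream peak in both R1881 lists (288 and 164), and a GC-rich intronic peak near its TSS in shFoxA1 EtOH (94) and shFoxA1 R1881 (49).

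KLK3, which encodes prostate-specific antigen, had a peak near -10.4 kb in all 4 lists, with scores of 158 in shEV EtOH, 85 in shEV R1881, 297 in shFoxA1 EtOH and 186 in shFoxA1 R1881. A second peak at -4031 bp (chromosome 19, 50850680 to 50851089 in shEV R1881) had scores of 135 and 102 in the R1881 lists, and a broad peak of 1692 bp covered the same place in shFoxA1 EtOH (49). Its neighbour KLK2 had a promoter peak in shFoxA1 R1881 (74) and none in the 3 other lists. TMPRSS2, the androgen-driven serine protease gene, had an intergenic peak near -70.1 kb in all 4 lists (105, 202, 429 and 175) and 0, 2, 3 and 4 peaks within 50 kb.

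**Figure D4:**
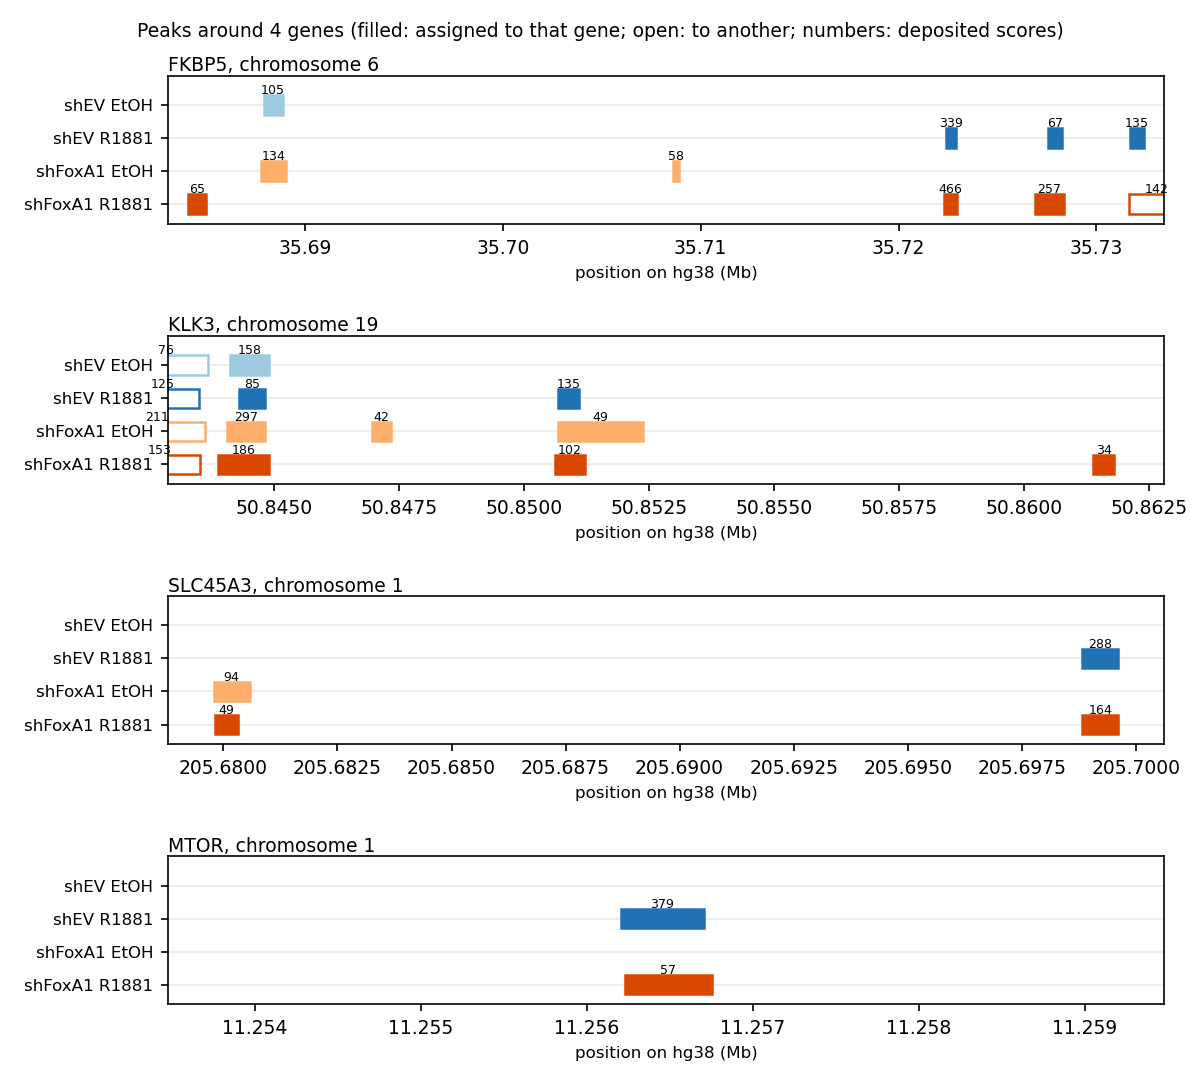
Peaks of the 4 libraries in windows around FKBP5, KLK3, SLC45A3 and MTOR (horizontal axes, position on hg38 in Mb); filled boxes are assigned to the named gene, open boxes to another gene, and the number above each box is its deposited score. The FKBP5 intron 1 peak (339 and 466) and the MTOR intron 4 peak (379 and 57) appear in the R1881 lists and not in the EtOH lists.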

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

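The tests in this part were chosen after the results were seen, apart from the R1881 odds ratio over all regions and the promoter shares of the 10000 highest-scoring peaks, which were set before the data were examined. With R1881 the mTOR pathway had a net of -5 peaks in shEV and 4 in shFoxA1, and genes of unrelated tissues had -1 and 5; these opposite signs stood out, and the difference between the hairpins was not tested. Among random genes with as many peaks the mTOR pathway lay on the low side with both hairpins, at percentiles 10.0 and 28.8, and the shFoxA1 pair as a whole had more gained peaks (57.2%) than the shEV pair (52.5%). Outside chromosomes 1 to 22, X and Y the lists held 556 peaks in shEV EtOH, 542 in shEV R1881, 566 in shFoxA1 EtOH and 538 in shFoxA1 R1881, sequences that no comparison used. In each list 1 of them spanned the whole mitochondrial genome, with deposited scores of 15546, 15315, 16246 and 15578.

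Promoters took a larger share of both shFoxA1 lists than of the shEV lists. The longer lists do not account for it by themselves, since among the 10000 highest-scoring peaks of each list the share still differed by 3.17 points in EtOH (2.37 to 3.97) and 2.97 points in R1881 (2.21 to 3.73). The odds ratio of a promoter peak was 1.33 in EtOH and 1.29 in R1881 over all peaks. Pooled over bins of GC content it was 0.993 (0.934 to 1.06) and 0.947 (0.891 to 1.01), so the difference was not seen at equal GC content. A candidate explanation is that the shFoxA1 libraries hold more GC-rich DNA of any kind, which may come from library preparation or from binding at CpG-rich sequence. The bins cannot separate this from more peaks close to a TSS, since such peaks are also annotated to classes other than promoter. Peaks within 1 kb of a TSS made up 14.7% of shEV EtOH, 12.8% of shEV R1881, 19.1% of shFoxA1 EtOH and 16.7% of shFoxA1 R1881. A difference between single preparations cannot be told apart from the knockdown, as each group is 1 library; libraries of the same hairpin differed by up to 1.42 points.

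Regions with a peak in both R1881 lists and neither EtOH list outnumbered the crossed combinations. Peaks that come and go by chance near the threshold would give an odds ratio of 1, and the value was 4.45. Pooled over 5 GC bins (Mantel-Haenszel) it was 4.19 (3.80 to 4.62). The single bins differed, from 2.27 (1.79 to 2.89) to 8.83 (6.82 to 11.4), so the pooled value is a summary only. Neither chance calls nor GC content in bins of this width accounts for the whole pattern. Near these regions lay 15 androgen-induced genes, where random genes with as many peaks gave 5.43. Regions in both EtOH lists only lay near 3, against 2.98 (percentile 53.4). Regions in both shEV lists only stood apart too, with 4 against 0.954 (percentile 99.3). The random genes were matched on peak number and not on expression or open chromatin. The 15 genes therefore cannot exclude a difference in depth or preparation between the R1881 and EtOH libraries. They would also be seen if mTOR, or chromatin that its immunoprecipitation recovers, gained at androgen targets with R1881 under both hairpins. That hypothesis was not tested apart from such a difference. Whether the input DNA changed at the same regions was not analysed here.

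Chromosomes 2 and 16 carried few peaks per Mb in every list, at most 0.581 (chromosome 2) and 0.550 (chromosome 16) of the value fitted from gene density on the 20 other autosomes. Counted per coding gene, chromosome 16 was at no more than 0.803 of the lowest other autosome and chromosome 2 at up to 1.33 times it. In peaks per Mb alone they were the lowest autosomes in both shEV lists. In the shFoxA1 lists chromosome 13 lay below chromosome 16, at 7.73 against 7.88 in EtOH and 8.55 against 9.42 in R1881. The chromosomes were picked as low in nearly the fitted measure, so being lowest in it cannot decide whether gene number accounts for them. A first form of the test took the highest of chromosomes 2, 13, 15 and 16 in peaks per coding gene, 1.21 times the median of the 18 other autosomes. That value came from chromosome 13 and does not bear on chromosomes 2 and 16. In shEV EtOH chromosome 13 had 1.83 peaks per coding gene, and chromosomes 2 and 16 had 0.920 and 0.493. Chromosome 16 was not short of genes, with 854 coding genes up to 90.1 Mb against 734 up to 133.8 Mb on chromosome 10. A lower DNA copy number could also give few peaks, and it cannot be told apart from fewer bound sites without the inputs, which were not analysed here; the fitted ratio differed between libraries by up to 1.25-fold. No biological explanation was tested.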

How the results depend on the processing

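Of the tests in this part, that of the 10000 highest-scoring peaks of a list against all peaks of the other and that of length-matched random lists were chosen after the data were seen, and the others before the data were examined. The order of the promoter shares, the odds ratios above 1 and the positive net of the androgen-induced genes with R1881 held at each setting at which they were computed, which for that net were the 2 other TSS distances and the 10000 highest-scoring peaks. In the knockdown pairs the androgen-induced net turned from 23 to -2 in EtOH and from 39 to -5 in R1881 with the 10000 highest-scoring peaks. Of the gene lists that stood apart, 2 turned with the 10000 highest-scoring peaks, and the androgen-repressed genes were at 0 there with both hairpins. Depth is unknown, which limits every comparison of list lengths. The number of peaks was little affected by leaving out low-complexity repeats (23653, 24823, 33639 and 38152 left). Equal list lengths bring the percent gained near 50 by construction, and fewer peaks or another TSS distance change the peaks counted near a list by construction; for the other values that moved the cause was not tested. Motifs in whole peaks and in the 10000 highest-scoring peaks, the alternatives of the motif comparison, were not run. Values follow in the order shEV EtOH, shEV R1881, shFoxA1 EtOH, shFoxA1 R1881 for libraries, and R1881 in shEV, R1881 in shFoxA1, knockdown in EtOH, knockdown in R1881 for pairs.

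With peaks at or above the median score of their list, the promoter share was 8.22%, 7.15%, 11.6% and 10.2%. The second list was shared at 63.3%, 67.6%, 75.4% and 74.7%, and gained peaks were 53.6%, 57.3%, 67.5% and 69.8% of those that differed. Regions in all 4 lists were 24.7%, those in both R1881 lists only 1835, and the odds ratios 6.08 for R1881 and 2.00 for the knockdown.

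With the 10000 highest-scoring peaks of each list, the promoter share was 7.70%, 6.71%, 10.9% and 9.68%. The second list was shared at 64.9%, 67.7%, 71.1% and 69.3%, and gained peaks were 50.05%, 50%, 50.1% and 50.2%. Regions in all 4 lists were 29.6%, those in both R1881 lists only 930, and the odds ratios 6.67 and 2.01. The net of the androgen-induced genes was 13 in shEV and 10 in shFoxA1. The ribosomal proteins turned from -11 to 2 with R1881 in shFoxA1, and the basal and mesenchymal markers from 11 to -1 in shEV. Asked of all peaks of the other list instead, the 10000 highest-scoring peaks of the second list were shared at 84.9%, 93.3%, 93.4% and 92.6%, and gained peaks were 57.1%, 64.3%, 59.6% and 59.9%.

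Without low-complexity repeats the promoter share was 10.3%, 9.35%, 13.2% and 11.6%, the second list was shared at 56.5%, 62.0%, 71.4% and 71.6%, and 18.3% of regions were in all 4 lists. With an overlap of at least 50%, the second list was shared at 51.9%, 56.8%, 67.5% and 68.3%, and gained peaks were 56.5% with R1881 in shFoxA1 and 70.6% for the knockdown in EtOH. With midpoints within 500 bp, 17.9% of regions were in all 4 lists. Within 10 kb of a TSS the androgen-induced net was 14 in shEV and 18 in shFoxA1, and at any distance 46 and 74. The luminal factors with R1881 in shFoxA1 stood at 9 within 10 kb and 44 at any distance, and the androgen-repressed genes at -3 and -14 in shEV and -4 and -19 in shFoxA1. Of 46 other net values, 43 moved with the 10000 highest-scoring peaks, 24 within 10 kb and 17 at any distance. Of 48 percentiles per library, 42 stayed on their side of the central 95% with length-matched lists, 5 moved inside and 1 moved outside.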

Other observations

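All tests in this part were chosen after the results were seen, and the features below were chosen after their values were seen. Among repeats, mTOR peaks fell on young L1 elements in 14.7% of the shEV EtOH list, 13.9% of shEV R1881, 13.1% of shFoxA1 EtOH and 14.3% of shFoxA1 R1881. L1PA5, a primate-specific L1 family, held 755, 720, 926 and 1155 peaks, the centromeric alpha satellite ALR 918, 808, 1001 and 935, and MER11A, an endogenous retroviral long terminal repeat, 379, 388, 445 and 430. Peaks in long terminal repeats recurred in all 4 lists more often than peaks outside repeats, in 62.1%, 63.0%, 49.7% and 47.4% of cases against 47.1%, 42.4%, 27.3% and 23.8%. Against peaks outside repeats with similar scores the difference was -3.47, 8.31, 1.83 and 8.46 points, so its direction in shEV EtOH turned. Short interspersed elements recurred in 34.5%, 29.3%, 22.8% and 15.4% of cases.

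Peaks annotated to transfer RNA genes numbered 57 in shEV EtOH, 58 in shEV R1881, 57 in shFoxA1 EtOH and 58 in shFoxA1 R1881. They were among the stronger peaks, with the median one above 86.6%, 90.6%, 90.8% and 94.6% of its list. On chromosome 6, which carries the largest human transfer RNA cluster, lay 36, 34, 33 and 36 of them. A region with a peak in all 4 lists held 56, 49, 45 and 42; all other peaks of similar score recurred in 81.3%, 81.3%, 76.6% and 84.2% of cases.

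Regions with a peak in both shEV lists and neither shFoxA1 list numbered 591. Counted by direct overlap instead, 633 shEV R1881 peaks had a peak in shEV EtOH and none in the shFoxA1 lists. Of these peaks 56.7% were in LINE elements. They lay within 50 kb of 4 androgen-induced genes, IQGAP2, PMEPA1, TPD52 and ZBTB10, against 0.954 for random genes with as many peaks (percentile 99.3). Regions in both shFoxA1 lists only lay near 11 androgen-induced genes, against 7.62 (percentile 91.6), IQGAP2 and ZBTB10 among them. By direct overlap this set held 4420 shFoxA1 R1881 peaks. Of these 20.3% lay in promoters, and their median GC content was 50.9%. Among its higher-scoring peaks near coding genes was a promoter peak at BASP1, a neuronal membrane and repressor gene (244).

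Chromosome 19, the most gene-dense, carried 20.9, 21.4, 30.1 and 33.6 peaks per Mb. Chromosome 2 carried 4.77, 4.92, 6.69 and 7.10, chromosome 16 carried 4.67, 5.34, 7.88 and 9.42, and chromosome X 1.89, 1.67, 2.83 and 2.83.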
